A study of Mus musculus with 15 samples.

How the data were processed

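B cells were purified ex vivo from lymph nodes of C57BL/6 mice, and total RNA from each sample was hybridised to an Affymetrix whole-genome mouse array after column extraction and labelling with a kit that amplifies in successive cycles, per the labels' protocols. The series held 15 arrays: 5 controls that carried floxed Traf2 or Traf3 alleles or the CD19-Cre transgene, 2 mice with Traf2 deleted in B cells, 2 with Traf3 deleted in B cells, 3 wildtype mice and 3 mice with a Baff transgene. The text of the study assigns the arrays to 3 processing days. Day 1 held controls 3 and 4 with knockout 1 of each genotype, day 2 held controls 1, 2 and 5 with knockout 2 of each genotype, and day 3 held the wildtype and Baff-transgenic mice. Control 3 was a pool. By their labels, controls 1, 2 and 3 carried floxed Traf2, control 5 floxed Traf3 and control 4 CD19-Cre. No control of day 2 thus carried Cre. An effect of Cre itself was not separable there from that of a deletion. Mice on day 1 were female and those on days 2 and 3 male, so sex was not separable from the day. Ages ran from 19 to 31 weeks on day 1, were 19 weeks on day 2 and ran from 12 to 15 weeks on day 3, so age was separable from the day only in part.

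Arrays were summarised with RMA, per the submitters' processing notes; its version was not given in the sources used here. The deposited values are linear ratios: in each of the 3 days, the median over the control arrays of that day was 1, within 1e-05, for all 45101 probe sets, so that each probe set appears to have been divided by its same-day control median. The unit was found from the values, since the labels do not state it. Comparisons within a day were unaffected by this division, while absolute brightness, signal over background and differences between days were lost. For that reason a filter on dim probe sets and a variance prior with an intensity trend, both planned, could not be run. No 2 arrays held the same values: at most 5575 of the 45101 values (12.4%) were identical between any of the 105 pairs of arrays.

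Probe sets were named from the platform annotation supplied with the series, which can be old. Of 45101 probe sets, 64 were control probe sets, 35890 were listed with a gene, 932 of these with several genes, and 9211 were not listed. Of the 34958 with 1 gene, 34945 could be used, and 34741 were brought to current symbols through Entrez identifiers in a RefSeq gene table of GRCm38.p6, which served only for names and for the order of neighbouring genes. Each of the 18193 genes was represented by 1 probe set. The plan had been to take the brightest probe set of a gene, which ratios do not allow. In its place a rule blind to the values was used for the 9010 genes with several: a RefSeq mRNA accession first, then the suffixes _at, _a_at, _s_at and _x_at in that order, then the lowest number.

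The log2 ratio was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). All 15 arrays shared one estimate of the spread, in a model with a mean for each day and an effect each for the Traf2 knockout, the Traf3 knockout and the Baff transgene, which left 9 residual and 4.995 prior degrees of freedom. The day was thus a block in every comparison. The comparisons were each genotype against its same-day controls, the mean of both knockouts against the controls, Traf2 against Traf3 knockout, the mean knockout effect minus the Baff-transgene effect, and the mean knockout effect on day 2 minus that on day 1. Unless another test is named, adjusted p-values are from limma after Benjamini-Hochberg adjustment over the 18193 genes, tests are two-sided, and genes with an adjusted p under 0.05 were called. Fold changes are limma estimates, and means with SDs are those of the ratios or log2 ratios of a group's arrays. Control and wildtype values were centred on their own same-day median. Their means therefore lie near 1 as ratios, and their SDs understate the spread among mice and are not comparable with those of the other groups. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.117 for each knockout, 0.0941 for both combined and 0.114 for the Baff transgene.

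The 23 gene lists were the alternative NF-kB pathway, NF-kB targets, BCL2 family and survival, TNF receptor and ligand families, marginal zone, follicular, immature and transitional, plasma cell and germinal centre B cell genes, cell cycle, B cell identity, MHC class II and antigen presentation, costimulation and activation, adhesion and homing, type I interferon response, glycolysis, immediate-early and stress response, and markers of T cells, NK cells, myeloid cells, dendritic cells, stromal and endothelial cells and erythroid cells. They were written from general knowledge and tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison; camera with a correlation estimated for each list and fry were alternatives. Some genes stand in more than 1 list.

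Groups, comparisons, tests, lists, the rule for named genes and all alternatives but 4 were fixed before the data were examined. The genes named were, for each genotype comparison, the 10 called genes with the largest rise and the 10 with the largest fall, provided that every knockout or transgenic array lay on that side of the same-day control mean. Up to 4 members of each list with the smallest adjusted p were added. For the differences between effects, 5 genes per direction were taken. Genes named outside this rule are said to have been chosen after their values were seen. The alternatives were quantile normalization or median centring, no day term, separate fits for days 1 and 2 and for day 3, the mean of all probe sets of a gene, no _x_at, _s_at or _a_at probe sets, array weights, age as a covariate, subsets of controls, each day alone, a replicate block on day 3 and leaving out each array. Gene counts and calls on leaving out an array were taken for arrays of the groups compared, although all arrays share the spread. Added after the data were seen were Baff-transgenic mice without control 5, all comparisons without both arrays high in heat-shock transcripts, a covariate for the 5′ over 3′ signal, and every probe set tested on its own. Where a left-out array leaves a genotype with 1 array, that array is assumed to vary like the others.

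Comparisons against the same controls were set beside 100 simulated draws of unchanged groups and beside splits of the controls. The procedure was tested on simulated data with independent normal noise, equal across arrays, in which 200 of the 18193 genes were changed. It recovered 56.14% of genes changed 1.5-fold, 88.24% of those changed 2-fold and 100% of those changed 4-fold in the Traf2 knockout comparison, with 11 false calls among 178. The shares were 57.14%, 86.89% and 100% for the Traf3 knockout, with 11 false calls among 173, and 64.18%, 91.8% and 100% for the Baff transgene, with 10 among 181. Real arrays differed in their spread, so these rates describe a simpler setting. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.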

Results

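Gene expression was measured in lymph node B cells of mice lacking Traf2 or Traf3 in B cells and of mice carrying a Baff transgene. TRAF2 and TRAF3 are adaptor proteins that hold the NF-kB-inducing kinase, and with it the alternative NF-kB pathway, in check, and BAFF is a TNF-family cytokine that keeps mature B cells alive and signals through that pathway. The comparisons address what the loss of either adaptor changes in B cells, and how far these changes resemble those of excess BAFF. There were 5 control, 2 Traf2 knockout and 2 Traf3 knockout arrays on days 1 and 2, and 3 wildtype and 3 Baff-transgenic arrays on day 3. Of the controls, only control 4, of day 1, carried Cre by its label. Values are ratios to the same-day control median.

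The targeted genes gave little check on the labels. The 1 listed probe set of Traf2 stood at ratios of 0.762 and 0.935 in the Traf2 knockout arrays, at 1, 1.01, 1.09, 0.913 and 0.694 in controls 1 to 5, and at 1.19 and 1.11 in the Traf3 knockout arrays. Its fold change in the Traf2 knockout was 0.904 (limma, unadjusted p = 0.350). It was lower in the Traf2 than in the Traf3 knockout array of each day but within the range of the controls, and a probe set outside the deleted part of a gene checks nothing. Probe sets of Traf3, Cd19 and Ddx3y were not listed and are not analysed here. The 3 probe sets of Tnfsf13b, which encodes BAFF, had fold changes of 1.02, 0.993 and 1.04 in the Baff-transgenic mice. Sex could not be checked from Xist, since each day held 1 sex and the ratios were centred within days.

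**Figure D1:**
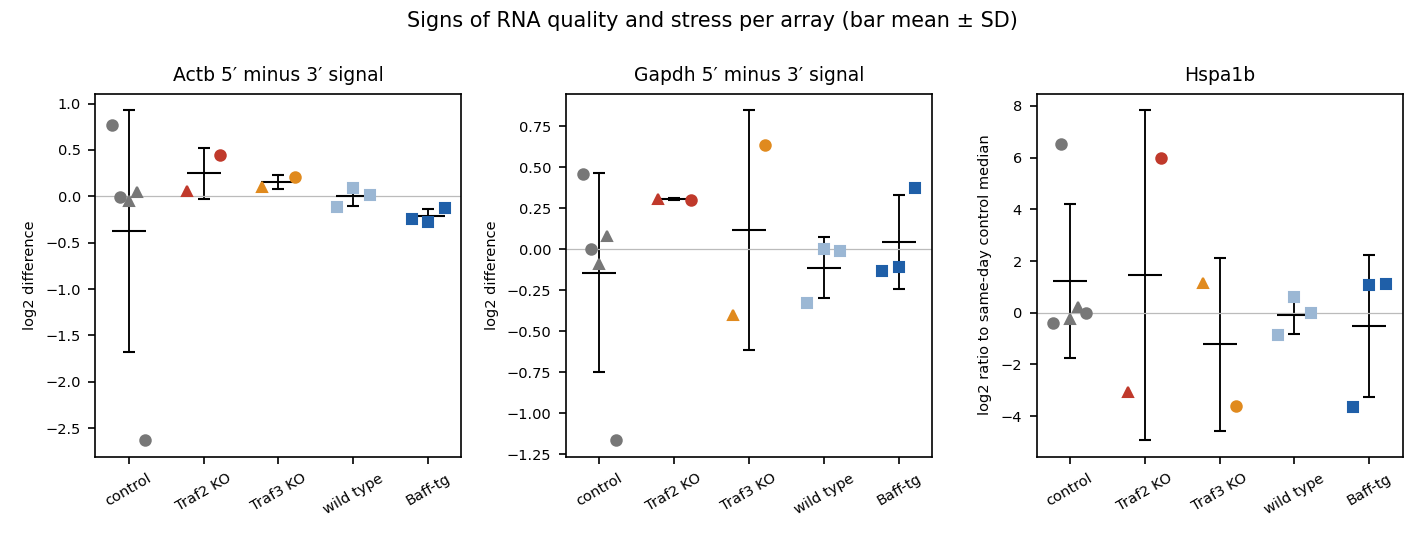
Signs of RNA quality per array: the log2 difference between 5′ and 3′ control probe sets and the log2 ratio of the heat-shock transcript Hspa1b, 1 point per array. Control 5 had the lowest Actb 5′ minus 3′ value, -2.63 against -0.275 or higher in the other arrays, and Hspa1b reached ratios of 92.01 in control 2 and 62.6 in Traf2 knockout 2.

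Loss of Traf2 raised Gpr34, a receptor for lysophosphatidylserine, 13.6-fold, to a mean ratio of 13.4 ± 0.44 (SD, n = 2) against 0.994 ± 0.13 in the controls (SD, n = 5). Pygl, the liver glycogen phosphorylase gene, rose 8.05-fold. The IL-9 receptor gene Il9r rose 5.78-fold, Rhbdf1, which encodes an inactive rhomboid protein, 6.71-fold, the choline kinase gene Chka 3.39-fold and Vwf, the von Willebrand factor gene, 3.11-fold. The genes that fell most included Pltp, a phospholipid transfer protein gene, to 0.438 of the control level, the sphingosine-1-phosphate transporter gene Spns2 to 0.473 and the lysosomal transporter gene Slc15a3 to 0.478. Cd93, a marker of immature B cells and long-lived plasma cells, fell to 0.492, the cytokine gene Il18 to 0.495, and Ezh2, the histone methyltransferase of the Polycomb complex, to 0.573.

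In all, 66 of 18193 genes changed in the Traf2 knockout, 48 higher and 18 lower, of which 18 and 7 by at least 2-fold. The log2 fold change of Gpr34 was 3.77 (SE 0.200, adjusted p = 4.49e-07), that of Pygl 3.01 (SE 0.182, adjusted p = 1.32e-06). Il9r stood at 2.53 (SE 0.251, adjusted p = 0.000305) and Vwf at 1.63 (SE 0.152, adjusted p = 0.000171). Spns2 changed by -1.08 (SE 0.133, adjusted p = 0.00165) and Cd93 by -1.02 (SE 0.137, adjusted p = 0.00285). Among the genes with the largest rise were also Thsd7a, Adm, Snrnp25 and Rsu1, with log2 fold changes of 2.19, 1.64, 1.52 and 1.44. Gpr155, Csrp2, Akap12 and Myadm were among those with the largest fall, with -1.12, -1.04, -0.93 and -0.85. By the rule for named genes, both knockout arrays lay on the same side of the controls for each of these. Other probe sets of Rsu1 (log2 -0.097 in 1 of them) and of Cd93 (0.27, 0.053 and 0.27) went the other way. Each day held 1 Traf2 knockout array, so that within a day the spread came only from control, wildtype and Baff-transgenic arrays; 20 genes passed within day 1 (15 higher, 5 lower) and 21 within day 2 (16 and 5). After quantile normalization 21 were higher and 2 lower, with separate fits for days 1 and 2 and for day 3 17 and 6, with array weights 81 and 42, with the 5′ over 3′ covariate 70 and 41, and with every probe set on its own 87 and 35. The count was 42 without control 2, 42 without control 3, 112 without control 5, 16 without Traf2 knockout 1, 23 without Traf2 knockout 2 and 14 without both arrays high in heat-shock transcripts, control 2 and Traf2 knockout 2. Of 28 named genes past the threshold, Ebi3, Gpr34, Il9r, Pygl, Rsu1 and Vwf stayed past it whichever control or Traf2 knockout array was left out. Calls were lost by 19 of the 28 without knockout 1, by 17 without knockout 2, and by 2, 10, 11 and 4 without controls 1, 2, 3 and 4.

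Among the gene lists, marginal zone B cell genes stood higher in the Traf2 knockout, by a median of 0.098 on the log2 scale (camera adjusted p = 0.000951, and adjusted p = 0.196 with an estimated correlation). Of 23 measured members 2 rose over all genes, Dusp16, a MAP kinase phosphatase gene (1.48-fold), and Pik3r4, which encodes a regulator of the lipid kinase Vps34 (1.53-fold). When adjusted over the list alone, 7 rose and none fell. Immature and transitional B cell genes stood lower (20 measured, median -0.11, adjusted p = 0.000915, and adjusted p = 0.196 with an estimated correlation). Cd93 fell over all genes, and 2 members fell when adjusted over the list alone. Plasma cell genes stood lower as well (27 measured, median -0.12, adjusted p = 0.00674, and adjusted p = 0.241 with an estimated correlation). Among them Cd93 and the syndecan gene Sdc1 fell, Sdc1 to 0.66 of control with 1 other probe set at log2 0.17, and 2 rose and 2 fell when adjusted over the list alone. Germinal centre genes had a median of -0.22 over 17 members (adjusted p = 0.00247, and adjusted p = 0.241 with an estimated correlation). The only member called over all genes nevertheless rose, Pou2af1, a coactivator gene of octamer-binding factors (1.66-fold). When adjusted over the list alone, 1 rose and 1 fell. Cell cycle genes had a median of -0.15 over 35 members (adjusted p = 0.00204, and adjusted p = 0.507 with an estimated correlation). None was called over all genes, and 1 rose when adjusted over the list alone.

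Immediate-early and stress response genes, which tissue handling induces within minutes, stood lower in the Traf2 knockout by a median of -0.32 over 31 members (camera adjusted p = 5.77e-05, and adjusted p = 0.36 with an estimated correlation). None was called over all genes, and 3 fell when adjusted over the list alone. Type I interferon response genes had a median of 0.21 over 31 members with none called either way (adjusted p = 0.00376, and adjusted p = 0.712 with an estimated correlation). NK cell markers had a median of -0.13 over 14 members (adjusted p = 0.00377, and adjusted p = 0.237 with an estimated correlation) and dendritic cell markers 0.058 over 16 (adjusted p = 0.0492, and adjusted p = 0.237 with an estimated correlation). Without Traf2 knockout 1, 7 of these 9 list calls ended, those of germinal centre and interferon genes being the exceptions. Without knockout 2 those of dendritic cell, germinal centre and interferon genes did, the last at a median of -0.17, and within day 1 alone the interferon median was -0.13. The dendritic cell call also ended without control 1, 3 or 4, the plasma cell call without control 1, the interferon call without control 3 and the marginal zone call without the _x_at, _s_at and _a_at probe sets.

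Loss of Traf3 also raised Gpr34, 15.6-fold, to a mean ratio of 15.4 ± 0.82 (SD, n = 2). Rhbdf1 rose 6.80-fold, Il9r 5.41-fold, Pygl 5.03-fold and Chka 3.38-fold. Ccr1, a chemokine receptor gene, rose 5.10-fold, Ackr3, which encodes a scavenging receptor for CXCL12, 2.97-fold, and Ffar2, a receptor for short-chain fatty acids, 2.73-fold. The call of Ccr1 ended without Traf3 knockout 2, that of Ackr3 without Traf3 knockout 2, control 2 or control 3, and that of Ffar2 without either Traf3 knockout or any of controls 1 to 4. The call of Chka ended without Traf3 knockout 1. The kinase gene Sgk1 fell to 0.469 of the control level, Niban3 to 0.539, Cd93 to 0.560, Slc15a3 to 0.567 and Spns2 to 0.578. Each of these falls lost its call without either Traf3 knockout or control 3, and Niban3 also without control 2 or 4.

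In the Traf3 knockout 61 genes changed, 51 higher and 10 lower, of which 21 and 1 by at least 2-fold. Log2 fold changes were 3.96 for Gpr34 (SE 0.200, adjusted p = 2.26e-07), 2.77 for Rhbdf1 (SE 0.328, adjusted p = 0.00169) and 2.44 for Il9r (SE 0.251, adjusted p = 0.000612). They were 2.33 for Pygl (SE 0.182, adjusted p = 3.82e-05), 2.35 for Ccr1 (SE 0.343, adjusted p = 0.00787) and -1.09 for Sgk1 (SE 0.191, adjusted p = 0.0259). Adm and Snrnp25 also rose, by 1.58 and 1.49, while Myadm, Ppm1e, Akap12, Ppp1r8 and Crybg3 fell, by -0.79, -0.79, -0.77, -0.75 and -0.66, and single other probe sets of Cd93 went the other way (0.048 and 0.097). Each day held 1 Traf3 knockout array too, and with the spread from the same other arrays 9 genes passed within day 1 (6 higher, 3 lower) and 30 within day 2 (25 and 5). After quantile normalization 22 were higher and 0 lower, with separate fits for days 1 and 2 and for day 3 5 and 0, and with array weights 20 and 0. The mean of all probe sets gave 86 and 26, the 5′ over 3′ covariate 81 and 26, and every probe set on its own 81 and 24. The count was 39 without control 2, 25 without control 3, 102 without control 5, 16 without Traf3 knockout 2 and 39 without both arrays high in heat-shock transcripts. Of 27 named genes past the threshold, Ebi3, Gpr34, Il9r, Pygl and Rhbdf1 stayed past it whichever control or Traf3 knockout array was left out. Calls were lost by 17 of them without knockout 1, by 19 without knockout 2, and by 2, 8, 17 and 4 without controls 1, 2, 3 and 4.

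The marginal zone list also stood higher in the Traf3 knockout (median 0.19, camera adjusted p = 0.000169, and adjusted p = 0.137 with an estimated correlation). Again Dusp16 (1.54-fold) and Pik3r4 (1.67-fold) rose over all genes, and 6 of 23 members rose when adjusted over the list alone. The immature and transitional list stood lower (median -0.15, adjusted p = 0.000169, and adjusted p = 0.137 with an estimated correlation), with Cd93 and Niban3 falling over all genes and when adjusted over the list alone. The immediate-early and stress list had a median of -0.32 with none called over all genes (adjusted p = 2.85e-06, and adjusted p = 0.444 with an estimated correlation). Glycolysis genes had a median of 0.15 over 18 members (adjusted p = 0.00518, and adjusted p = 0.391 with an estimated correlation). That of MHC class II genes was 0.12 over 16 members (adjusted p = 0.0439, and adjusted p = 0.839 with an estimated correlation) and that of interferon genes 0.19 (adjusted p = 0.0404, and adjusted p = 0.874 with an estimated correlation). None of these 3 lists had a member called over all genes. T cell markers had a median of -0.087 over 21 members (adjusted p = 0.000751, and adjusted p = 0.599 with an estimated correlation) and NK cell markers -0.062 (adjusted p = 0.0492, and adjusted p = 0.473 with an estimated correlation). Without Traf3 knockout 2 the calls of the MHC class II (median -0.021), NK, T cell, glycolysis, immature and marginal zone lists ended. Calls also ended without knockout 1, those of glycolysis and interferon genes, without control 1, 2 or 3 those of NK and interferon genes, and without control 5 those of MHC class II and NK genes. Within day 1 alone the MHC class II median was -0.057. The marginal zone call ended without the _x_at, _s_at and _a_at probe sets.

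Across both knockouts, several genes known as NF-kB targets rose. Traf1, an NF-kB-induced adaptor gene, rose 2.01-fold, with log2 ratios of 0.89 ± 0.0047 in the Traf2 knockout and 1.02 ± 0.15 in the Traf3 knockout (SD, n = 2 each) against -0.05 ± 0.18 in the controls (SD, n = 5). Ebi3, a cytokine subunit gene, rose 1.98-fold, Lta, which encodes lymphotoxin alpha, 1.64-fold and Nfkb2, the precursor of the alternative pathway's own subunit, 1.66-fold. Among surface molecules of marginal zone B cells, Cd9 rose 2.38-fold and the complement receptor gene Cr2 1.33-fold. The transcription factor gene Fos fell to 0.272 of the control level. Its log2 ratios were -2.18 ± 1.02 and -1.42 ± 1.03 in the Traf2 and Traf3 knockouts (SD, n = 2 each) against 0.09 ± 0.40 in the controls (SD, n = 5).

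With both knockouts combined, 166 genes changed, 126 higher and 40 lower, 29 and 3 of them by at least 2-fold. The largest rises were those of Gpr34 (log2 3.87, SE 0.161, adjusted p = 1.61e-08), Rhbdf1 (2.76, SE 0.264, adjusted p = 0.000122) and Pygl (2.67, SE 0.147, adjusted p = 3.48e-07). Next came Il9r (2.48, SE 0.201, adjusted p = 3.03e-05) and Ccr1 (2.01, SE 0.275, adjusted p = 0.00224), then Chka, Thsd7a, Adm, Snrnp25 and Nebl at 1.76, 1.70, 1.61, 1.51 and 1.48. The largest falls were those of Fos (-1.88, SE 0.387, adjusted p = 0.0361), Wfdc17 (-1.21), Btg1 (-1.10), Sgk1 (-0.96), Slc15a3 (-0.94), Spns2 (-0.94), Pltp (-0.93), Cd93 (-0.93), Il18 (-0.89) and Csrp2 (-0.89). Single other probe sets went the other way for Btg1 (0.070 and 0.059) and Cd93 (0.16 and 0.18). Those of Ccr1 and Thsd7a rose less than the ones used, by 0.47 and 0.30, while that of Adm rose by 1.61. Within day 1 alone 31 genes passed (24 higher, 7 lower) and within day 2 alone 38 (31 and 7), with 1 array of each knockout and the spread from the other groups. After quantile normalization 59 were higher and 12 lower, with separate fits for days 1 and 2 and for day 3 38 and 12, with the mean of all probe sets 183 and 75, and with the 5′ over 3′ covariate 164 and 93. Across genes the effects of both days had a Pearson r of 0.504 and a Spearman rho of 0.298. The count was 106 without control 2, 89 without control 3, 100 without Traf2 knockout 2 and 74 without both arrays high in heat-shock transcripts. Of 37 named genes past the threshold, 24 stayed past it whichever control or knockout array was left out, while Btg1, Cd9, Cr2, Ell2, Fos, Nebl, Nfkb2, Pdcd1lg2, Pdia4, Pltp, Slamf1, Spib and Wfdc17 did not. Of these, 8, 8, 5 and 12 lost their call without Traf2 knockouts 1 and 2 and Traf3 knockouts 1 and 2, and 6, 12 and 6 without controls 2, 3 and 4.

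**Figure D2:**
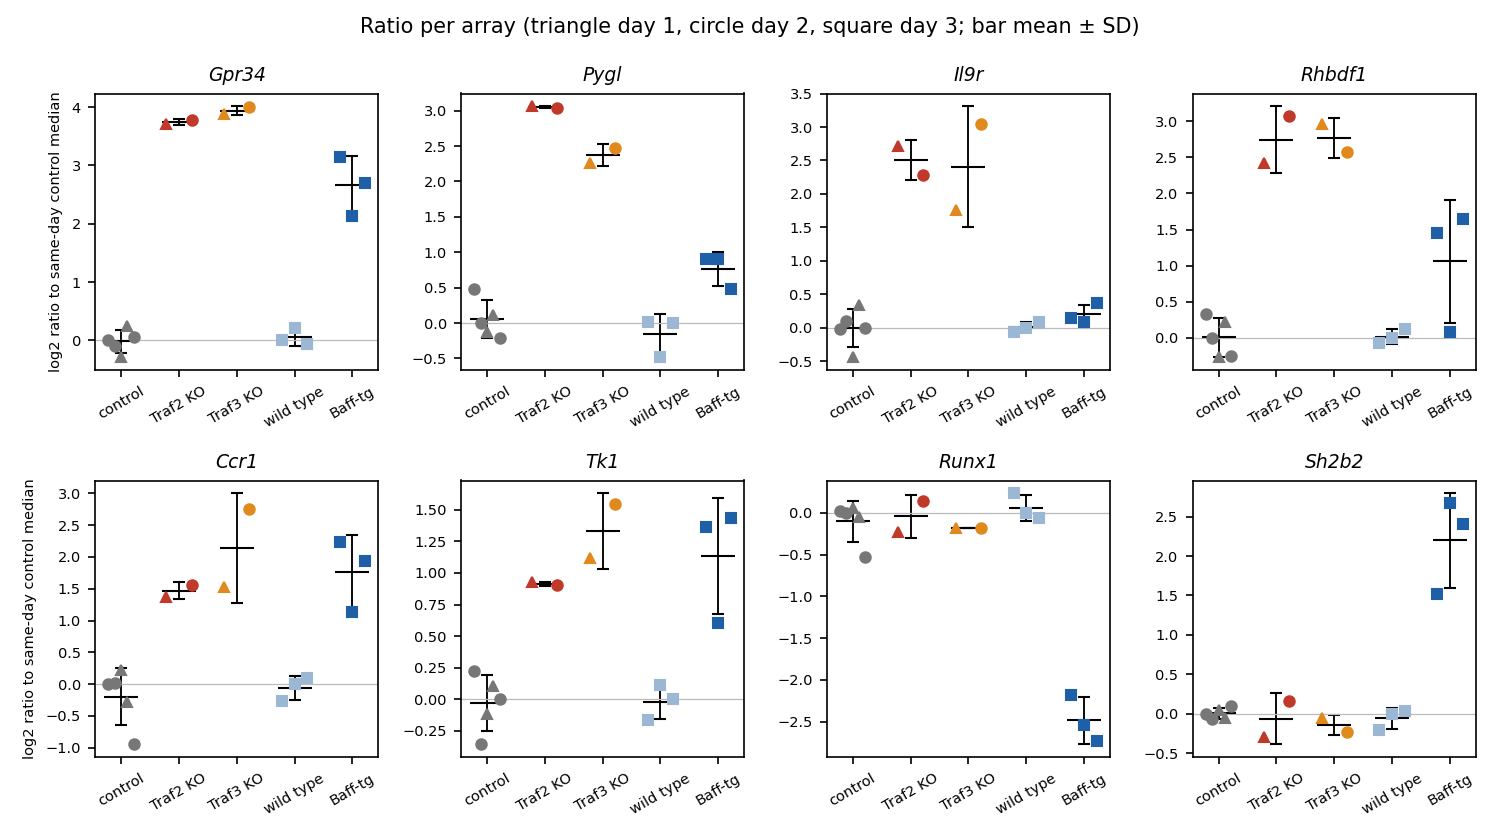
Log2 ratio to the same-day controls of 8 named genes, 1 point per array by group and day, with group means and SDs. The SDs of controls and wildtype mice are narrowed by the centring on their own median. Gpr34, Pygl and Il9r lay above the controls in all 4 knockout arrays, at log2 fold changes of 3.87, 2.67 and 2.48 with both knockouts combined, while Runx1 lay lower in all 3 Baff-transgenic arrays at -2.54.

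The alternative NF-kB list had 2 of 14 members called over all genes in the combined comparison, Traf1 and Nfkb2, and 4 rose and 1 fell when adjusted over the list alone. As a list it did not pass (median 0.11, camera adjusted p = 0.135, and adjusted p = 0.613 with an estimated correlation). Of 38 NF-kB targets, Nfkb2, Traf1, Lta and Ebi3 rose over all genes, and 8 rose and 1 fell when adjusted over the list alone. The list did not pass (adjusted p = 0.472, and adjusted p = 0.731 with an estimated correlation), and its median, -0.013, and its mean, 0.063, differed in sign. Marginal zone genes passed with 5 of 23 members higher over all genes, Cr2, Cd9, Dusp16 (1.51-fold), Pik3r4 (1.60-fold) and Asb2 (log2 0.59), and 8 when adjusted over the list alone (median 0.11, adjusted p = 0.000124, and adjusted p = 0.0984 with an estimated correlation). The other probe set of Dusp16 stood at log2 0.098, against 0.5925 in the one used. Immature and transitional genes passed with Cd93 and Niban3 (0.557 of control) lower both over all genes and when adjusted over the list alone (median -0.094, adjusted p = 7.05e-05, and adjusted p = 0.0984 with an estimated correlation). The immediate-early and stress list had a median of -0.34, with Fos lower over all genes and 3 members lower when adjusted over the list alone (adjusted p = 3.69e-07, and adjusted p = 0.329 with an estimated correlation). Hspa1b, a member, stood at 92.01 in control 2 and 62.6 in Traf2 knockout 2, and the list's median without these arrays was -0.31. Germinal centre genes had a median of -0.15 (adjusted p = 0.0408, and adjusted p = 0.507 with an estimated correlation), although the only member called over all genes, Pou2af1, rose 1.69-fold, and 1 rose when adjusted over the list alone. Interferon genes had a median of 0.17 with none called (adjusted p = 0.00421, and adjusted p = 0.685 with an estimated correlation).

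T cell markers had a median of -0.11 in the combined comparison (camera adjusted p = 0.00248, and adjusted p = 0.507 with an estimated correlation). NK cell markers had a median of -0.096, with 1 member falling when adjusted over the list alone (adjusted p = 0.00652, and adjusted p = 0.311 with an estimated correlation). The germinal centre call ended without Traf2 knockout 2, either Traf3 knockout, control 3 or control 5, and that of interferon genes without Traf2 knockout 2 (median 0.0019, with the direction of the test reversed), Traf3 knockout 1 or control 3. The T cell call ended without Traf2 knockout 1, Traf3 knockout 2 or control 3, the NK call without Traf3 knockout 2 or control 3, and the marginal zone call without the _x_at, _s_at and _a_at probe sets.

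The remaining lists did not pass in the combined comparison. Plasma cell genes had Ell2 and Pdia4 higher and Sdc1 and Cd93 lower over all genes, and 3 higher and 2 lower when adjusted over the list alone. Other probe sets of Ell2, Pdia4 and Sdc1 had the opposite sign, at log2 -0.049, -0.11 and 0.020. The list did not pass (median -0.083, adjusted p = 0.0892, and adjusted p = 0.507 with an estimated correlation). Cell cycle genes had Tk1, the thymidine kinase gene, 2.23-fold higher and no other call (median -0.096, adjusted p = 0.0626, and adjusted p = 0.685 with an estimated correlation). B cell identity genes had Pou2af1 and Spib called, at log2 0.76 and 0.40 (median 0.042, adjusted p = 0.198, and adjusted p = 0.731 with an estimated correlation). Among costimulatory genes Pdcd1lg2, which encodes a ligand of PD-1, rose 1.68-fold and Slamf1 fell to 0.658, with 4 rising and 1 falling when adjusted over the list alone (median -0.001, adjusted p = 0.578, and adjusted p = 0.706 with an estimated correlation). The TNF receptor and ligand list had Lta alone called over all genes, as higher (median -0.0047, mean 0.015, adjusted p = 0.748, and adjusted p = 0.751 with an estimated correlation). The BCL2 family had no call over all genes (median -0.0041, mean 0.063, adjusted p = 0.761, and adjusted p = 0.777 with an estimated correlation). Medians were -0.076 for follicular, 0.11 for MHC class II, 0.034 for adhesion and 0.086 for glycolysis genes (adjusted p = 0.139, 0.0626, 0.748 and 0.0626, and adjusted p = 0.729, 0.706, 0.849 and 0.507 with an estimated correlation). Myeloid, dendritic cell, stromal and erythroid markers had medians of 0.012, 0.075, -0.028 and 0.0086 (adjusted p = 0.544, 0.0892, 0.806 and 0.531, and adjusted p = 0.751, 0.329, 0.878 and 0.685 with an estimated correlation). The mean of the erythroid markers was of the other sign, -0.10. When adjusted over the list alone, 3 glycolysis genes, 2 B cell identity genes and 1 cell cycle gene rose, 1 gene of the BCL2 family rose, 1 of the TNF receptor and ligand list rose and 1 fell, and 2 erythroid genes fell.

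**Figure D3:**
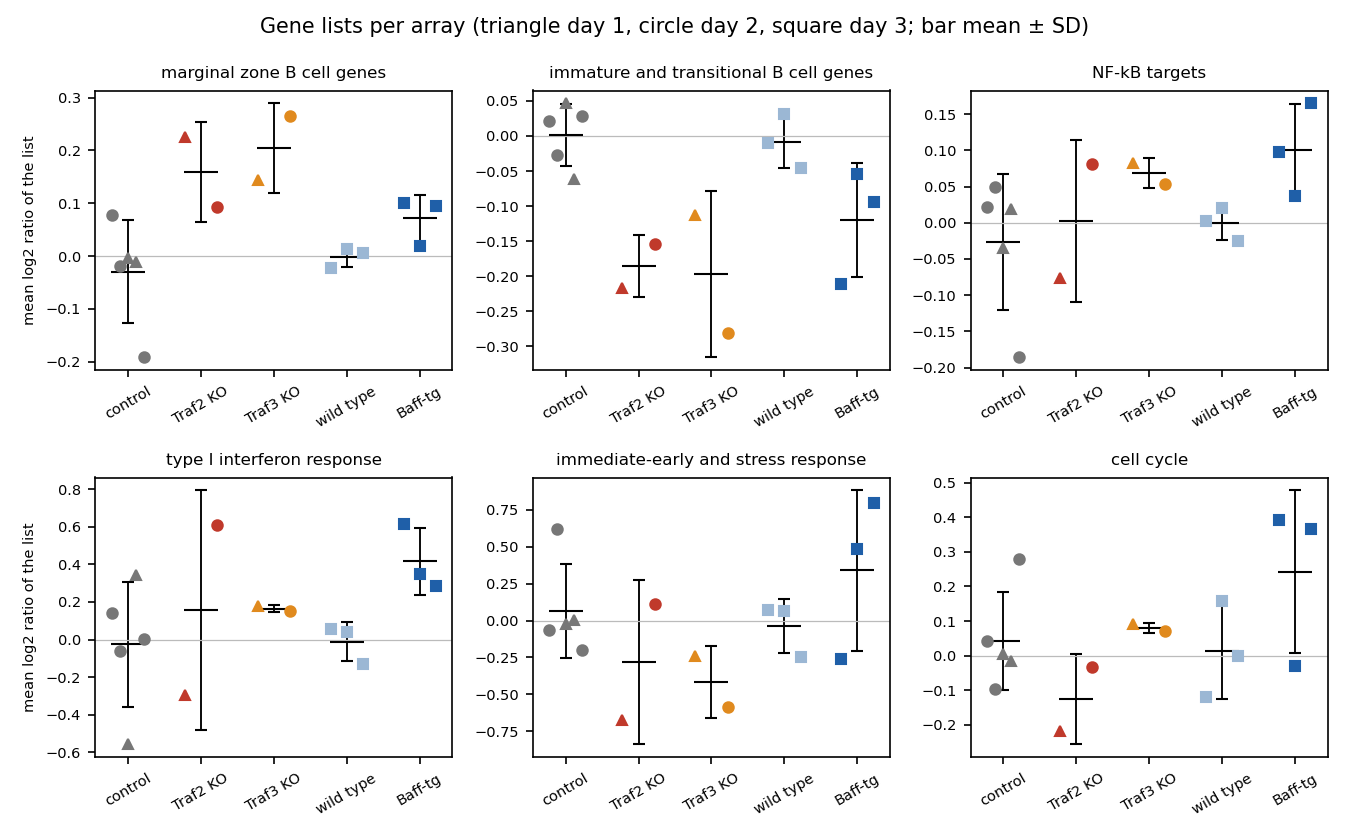
Mean log2 ratio of 6 gene lists in each array, 1 point per array, by group. The immediate-early and stress list lay at -0.67 and -0.59 in Traf2 knockout 1 and Traf3 knockout 2, at 0.11 and -0.24 in Traf2 knockout 2 and Traf3 knockout 1, and at 0.62 in control 2.

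Traf2 and Traf3 knockouts were then compared with each other. No gene differed between them by limma (0 of 18193, smallest adjusted p = 1), with 469 at an unadjusted p under 0.05. The nearest were Vwf, 0.93 higher on the log2 scale in the Traf2 knockout (SE 0.181, unadjusted p = 0.000145, adjusted p = 1), and Slc16a1, a lactate transporter gene, at -0.56 (SE 0.125, unadjusted p = 0.000533, adjusted p = 1). They were followed by Atg2b, Rnf24, Ccn1 and Cfap43 at 0.59, 0.43, 0.39 and 0.41 and by Chid1, Meis3, Get3 and Ldlrad3 at -0.50, -0.50, -0.42 and -0.42. The 89 genes called in either knockout all had the same sign in both. Their median difference was 0.183 in size against a median half-width of 0.346 for the 95% interval. The largest was that of Thsd7a, 0.978 (0.25 to 1.71), so that differences of this order stay open. The 469 genes are a smaller share than the 0.05 that unchanged, independent genes would give. Differences between the arrays of a genotype on different days enter the spread of this test and widen it. The absence of calls thus does not show that both knockouts acted alike. Without Traf3 knockout 1, 2 genes passed.

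Both knockouts called 33 genes higher and 5 lower in common, against 0.135 and 0.0099 for independent lists. They shared their controls: across genes, which are not independent replicates, the effects had r = 0.660 and rho = 0.521, while simulated unchanged groups gave a mean r of 0.287 and a range of -0.584 to 0.845 that includes the observed value. The number of genes called in both was 0 in each of the 100 simulated draws, against 38 observed. As no gene was changed in these draws, this covers only overlap from the shared controls alone. The covariance was 0.0210 against a simulated mean of 0.00617, a difference of 0.0148, and lay within the simulated range of -0.00701 to 0.0227. With the controls split so that none was shared, r was 0.231 to 0.429 over 12 splits with a median of 0.339, and the covariance 0.00916 to 0.0155. Within day 1 alone r was 0.278 and within day 2 alone 0.282. Among the lists, plasma cell, germinal centre, cell cycle and glycolysis genes stood lower in the Traf2 than in the Traf3 knockout, by medians of -0.10, -0.11, -0.15 and -0.097 (camera adjusted p = 0.0374, 0.0374, 0.00924 and 0.0374, and adjusted p = 0.859, 0.859, 0.943 and 0.859 with an estimated correlation). When adjusted over the list alone, 1 glycolysis gene was lower in the Traf2 knockout. All 4 list calls ended without Traf2 knockout 1, Traf3 knockout 1 or Traf3 knockout 2, and that of germinal centre genes without Traf2 knockout 2.

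In Baff-transgenic mice, Gpr34 again rose most, 6.10-fold, to a mean ratio of 6.57 ± 2.2 against 1.04 ± 0.1 in wildtype mice (SD, n = 3 each), and Ccr1 rose 3.54-fold. Prelid2 rose 5.79-fold, the adapter gene Sh2b2 4.78-fold, Ap1s3, which encodes a subunit of a clathrin adaptor complex, 2.85-fold, the epithelial adhesion gene Epcam 2.25-fold and Tk1 2.22-fold. The transcription factor gene Runx1 fell to 0.172 of the wildtype level and Col23a1, a collagen gene, to 0.340. Cd200, an inhibitory surface glycoprotein gene, fell to 0.376 and Phykpl to 0.406. Several of these changes were small or absent in most other probe sets of the gene: the median log2 change of the other probe sets was -0.03 for Runx1, 0.13 for Prelid2, 0.17 for Sh2b2 and -0.02 for Epcam. It was -0.28 for Col23a1 and -0.31 for Phykpl. Of the 5 other probe sets of Runx1, the one that fell most lay at -1.02.

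In the Baff-transgenic mice 35 genes changed, 25 higher and 10 lower, of which 11 and 5 by at least 2-fold. The log2 fold change was 2.61 for Gpr34 (SE 0.195, adjusted p = 1.76e-05), 2.53 for Prelid2 (SE 0.224, adjusted p = 8.94e-05). It was -2.54 for Runx1 (SE 0.170, adjusted p = 9.83e-06), -1.56 for Col23a1 (SE 0.118, adjusted p = 1.76e-05) and -1.41 for Cd200 (SE 0.180, adjusted p = 0.0044). Tmco6, Ehd3 and Paip1 also rose, by 1.43, 1.24 and 1.22, and Prag1, Myadm, Stk11ip, 2310001H17Rik, Gramd4 and Carns1 fell, by -1.21, -0.98, -0.91, -0.67, -0.63 and -0.55. Single other probe sets went the other way for Runx1 (0.036 and 0.10), Tmco6 (-0.084), Paip1 (-0.12) and Epcam (-0.017). After quantile normalization 6 were higher and 6 lower, with separate fits for days 1 and 2 and for day 3 60 and 34, and with array weights 80 and 55. The mean of all probe sets gave 37 and 16, the 5′ over 3′ covariate 48 and 26, and every probe set on its own 45 and 21. The count was 14, 8 and 9 without wildtype 1, 2 and 3, 22 without Baff-transgenic mouse 1, 14 without mouse 3, and 74 when control 5, an array of another day that enters through the shared spread, was left out. Of 20 named genes past the threshold, Ap1s3, Cd200, Col23a1, Gpr34, Prelid2, Runx1 and Sh2b2 stayed past it whichever wildtype or Baff-transgenic array was left out, and without control 5. Of these 20, 9, 2 and 11 lost their call without Baff-transgenic mice 1, 2 and 3, and 9, 13 and 11 without wildtype mice 1, 2 and 3.

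Type I interferon response genes stood higher in the Baff-transgenic mice by a median of 0.30 over 31 members (camera adjusted p = 1.13e-09, and adjusted p = 0.315 with an estimated correlation). None was called over all genes, with Oas2 at 1.12, Oas1a at 1.06 and Mx2 at 0.93, and 3 rose when adjusted over the list alone. The immediate-early and stress list had a median of 0.19 with none called (adjusted p = 3.98e-07, and adjusted p = 0.312 with an estimated correlation). Its mean log2 ratio was -0.26, 0.49 and 0.80 in Baff-transgenic mice 1, 2 and 3, so the mice went both ways. Cell cycle genes had a median of 0.11 with Tk1 called over all genes and 2 rising when adjusted over the list alone (adjusted p = 5.38e-05, and adjusted p = 0.315 with an estimated correlation). Myeloid cell markers had a median of 0.054 over 31 members, with Apoe at 1.10 and the lysozyme gene Lyz2 at 0.76 (adjusted p = 0.00511, and adjusted p = 0.312 with an estimated correlation). None was called over all genes, and 5 rose when adjusted over the list alone. NF-kB targets had a median of 0.060 (adjusted p = 0.0301, and adjusted p = 0.315 with an estimated correlation). None was called over all genes, with Traf1 at log2 0.67 and Tnip1 at 0.52, and 2 rose when adjusted over the list alone. Germinal centre genes had a median of 0.16 with none called (adjusted p = 0.0471, and adjusted p = 0.321 with an estimated correlation). Follicular genes had a median of -0.11 over 15 members, with Cd200 lower over all genes and when adjusted over the list alone (adjusted p = 0.0471, and adjusted p = 0.675 with an estimated correlation). The calls of NF-kB targets, follicular and germinal centre genes ended without Baff-transgenic mouse 1 or 3, and that of myeloid markers without mouse 3. Calls also ended without wildtype mice, those of follicular and germinal centre genes without wildtype 1, that of follicular genes without wildtype 2 and that of NF-kB targets without wildtype 3.

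The knockouts and the Baff transgene had separate controls but shared one estimate of the spread, so their calls were not independent. Both called 8 genes higher in common, Carmil1, Ccr1, Epcam, Faah, Gpr34, Ppfibp2, Ptpn14 and Tk1, and 2 lower, Myadm and Prag1. Independent lists, which these are not, would share 0.173 and 0.022. Gpr34 rose 14.6-fold in the knockouts and 6.10-fold with the transgene, Ccr1 4.04-fold and 3.54-fold, and Tk1 2.23-fold and 2.22-fold. The other probe sets of Epcam and Prag1 had median log2 changes of -0.04 and 0.0064 in the knockouts and of -0.02 and -0.07 with the transgene. That of Ccr1 moved by 0.47 and 0.78, against 2.014 and 1.825 in the one used. Those of Faah and Ptpn14 rose by medians of 0.57 and 1.30 in the knockouts and of 0.31 and 1.01 with the transgene. Of the 166 genes called in the knockouts, 150 (90.4%) had the same sign in the Baff-transgenic mice, with a median ratio of the effects of 0.464, and of the 35 called with the transgene 29 (82.9%) had the same sign in the knockouts. Across all genes the effects had r = 0.247, rho = 0.0982 and a covariance of 0.00650; for the Traf2 and Traf3 knockouts alone r was 0.229 and 0.222. Since the knockouts were measured on days 1 and 2 and the transgene on day 3, day, age and sex moved with this comparison.

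**Figure D4:**
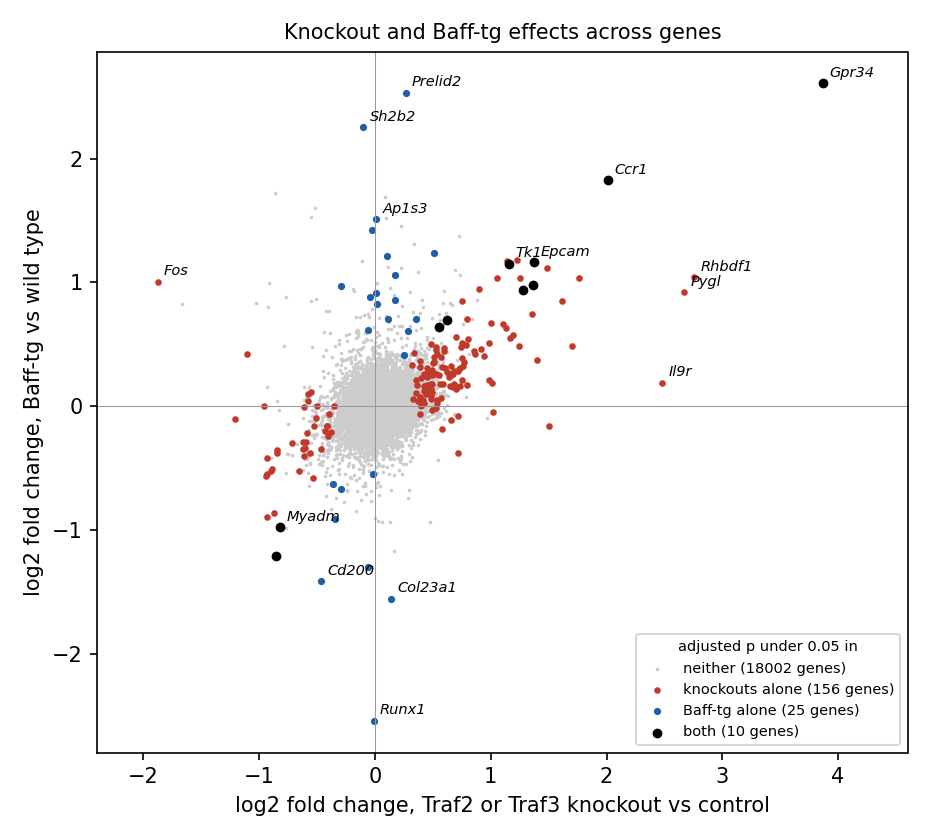
Log2 fold change with both knockouts combined against that in Baff-transgenic mice, 1 point per gene. Gpr34 lay farthest out in both, at 3.87 and 2.61, while Il9r and Pygl lay along the knockout axis and Prelid2, Sh2b2, Runx1 and Col23a1 along the Baff axis.

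The effects themselves differed for 7 genes. Il9r rose in the knockouts but lay at a log2 change of 0.19 with the transgene, a difference of 2.29 (SE 0.316, adjusted p = 0.011), and Pygl lay at 2.67 against 0.92, a difference of 1.75 (SE 0.230, adjusted p = 0.009). Runx1 and Col23a1 were lower with the transgene, by differences of 2.53 (SE 0.221, adjusted p = 0.000252) and 1.69 (SE 0.153, adjusted p = 0.000252). Sh2b2, Prelid2 and Ap1s3 were higher with it, by differences of -2.36, -2.27 and -1.50 (adjusted p = 0.00448, 0.00811 and 0.011). In the other probe sets of Runx1, Col23a1, Sh2b2 and Prelid2 the median log2 change with the transgene was only -0.03, -0.28, 0.17 and 0.13. After quantile normalization 1 gene was higher and 0 lower, with array weights 13 and 4, with the mean of all probe sets 8 and 7, with the 5′ over 3′ covariate 8 and 4, and with every probe set on its own 8 and 8. The count was 12 without control 5, 11 without Baff-transgenic mouse 1 and 3 without wildtype 1 or wildtype 3. Il9r, Prelid2, Pygl and Ap1s3 lost their call without wildtype 1 or 3, Il9r also without wildtype 2 or Baff-transgenic mouse 2, and Ap1s3 without mouse 3 or Traf3 knockout 2.

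Between the knockout and transgene effects 9 lists differed. Immediate-early and stress genes stood lower in the knockouts relative to the transgene by a median of -0.49, with 10 members lower when adjusted over the list alone (camera adjusted p = 2.13e-15, and adjusted p = 0.275 with an estimated correlation). Cell cycle, germinal centre, interferon, T cell and NK genes also stood relatively lower, by -0.14, -0.22, -0.14, -0.081 and -0.10 (adjusted p = 2.43e-06, 0.00202, 0.0167, 0.0167 and 0.0229, and adjusted p = 0.313, 0.313, 0.657, 0.617 and 0.313 with an estimated correlation). Marginal zone, B cell identity and MHC class II genes stood relatively higher, by 0.20, 0.16 and 0.18 (adjusted p = 0.0472, 0.022 and 0.019, and adjusted p = 0.313, 0.617 and 0.617 with an estimated correlation). Up to 6 of these calls ended on leaving out an array, none without control 1 or Traf3 knockout 1, 6 without Traf3 knockout 2, and 5 without Traf2 knockout 1 or Baff-transgenic mouse 3. The number was 3 without control 3 or 5, 2 without wildtype 3, and 1 each without Baff-transgenic mouse 1 or 2, Traf2 knockout 2, control 2 or 4, or wildtype 1 or 2.

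Whether the knockout effect differed between processing days, and with them between sexes, was tested last. No gene passed by limma (0 of 18193, smallest adjusted p = 0.999746), with 227 at an unadjusted p under 0.05. These are a smaller share than the 0.05 that unchanged, independent genes would give, so the absence of calls does not show equal effects. The genes nearest to passing were Pxdc1 at -0.74 (SE 0.167, unadjusted p = 0.000879) and Serinc3 at 0.72 (SE 0.166, unadjusted p = 0.000991). Next came H2-T24, of a family with near-identical copies, Tfb1m, Sspn and Zfp263 at 0.93, 0.66, 0.64 and 0.47, and Trem3, Tuba8, Serpina1c and Gm3764 at -0.60, -0.53, -0.51 and -0.44. Interferon, MHC class II and B cell identity genes stood relatively higher on day 2, by medians of 0.30, 0.24 and 0.18 (camera adjusted p = 6.39e-05, 0.00124 and 0.00124, and adjusted p = 0.843 for each with an estimated correlation). All 3 calls ended without control 4, where the interferon median was -0.059, and those of B cell identity and MHC class II genes without control 5.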

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

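The tests of the other probe sets, of neighbouring genes, of control 5 and of the resemblance between knockout arrays were chosen after the results were seen, and the last replaced a first version whose genes had been picked on all 4 knockout arrays; the counts over other splits of the samples were chosen before, but for the splits of the knockout labels with those of day 3 kept.

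In the group of 5 controls, 10 of 73 measures held an array whose gap to the next exceeded 0.71 of the range. For 5 independent values this limit marks about 1 in 20 groups. The ratios were centred within days and so were not independent, and that rate cannot be assumed here. Of the 10, 7 lay in control 5 and 2 in control 2. In control 5 these were the log2 ratio of Nfkb2 at -0.71, the mean log2 ratios of the BCL2 family at -0.096, germinal centre genes at 0.39, MHC class II genes at -0.70, adhesion genes at -0.29 and stromal markers at 0.065, and the Actb 5′ minus 3′ signal at -2.63. In control 2 they were Ppp1r8 at 0.36 and the immediate-early and stress list at 0.62, and in control 1 dendritic cell markers at -0.027.

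Control 5, a Traf3-floxed mouse of day 2, stood apart from the other arrays, with a weight of 0.25 among limma's array weights. Whether that sample held a lower share of B cells cannot be decided here. Its B cell identity list was low, at -0.356, and the median of the 6 lists of other cell types was 0.0123. These stood at 0.021, -0.043, 0.0032, -0.0032, 0.065 and 0.074 for T, NK, myeloid, dendritic, stromal and erythroid cells. Ratios cannot show whether such markers lay above background in purified B cells, and the low 5′ signal may move the lists too. Degraded RNA is a candidate explanation, since the Actb 5′ minus 3′ value of control 5, -2.63, lay below -0.275, the lowest of the other 14 arrays. It was the only Traf3-floxed control, so its genotype also stays open, untested.

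The genes called in Baff-transgenic mice moved less in their other probe sets: over the 21 with several, the median share of the change seen in the others was 0.0952, against 0.483 over 74 genes called in the knockouts, and 13 of 21 lay under 0.25 against 21 of 74. A chromosome region carried along with the transgene is argued against as the whole cause, since only 3 pairs of called genes lay within 50 genes of each other, the median of 1000 random sets being 3 and their 95th percentile 6; 6 of 34 placed genes had such a neighbour, among them the adjacent Col23a1 and Phykpl, both lower. A sequence or transcript difference under the probe set used may account for part of these calls, as the low share is what it predicts. A change in single transcripts of these genes through the transgene stays open.

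The knockout arrays resembled each other across genotypes and days, with r across genes of 0.457 between Traf2 knockout 1 and Traf3 knockout 2 and 0.519 between Traf2 knockout 2 and Traf3 knockout 1, against 0.287 within Traf2 and 0.0635 within Traf3, and 0.278 and 0.282 within days, where controls are shared. Dividing the 4 arrays the crossed way, which was chosen after these correlations were seen and so only restates them, called 74 genes by limma (2807 at an unadjusted p under 0.05), against 0 the labelled way (469 at an unadjusted p under 0.05). A score of the 100 genes that differ most between both Traf2 knockout arrays differed by 0.565 between the Traf3 knockout arrays, the crossed way round, against ranges of 0.153 among Baff-transgenic and 0.147 among wildtype mice. Labels exchanged on 1 of the days and a state of single mice or of their RNA cannot be told apart: no probe set here clearly marks either deletion, and control 5, with its low 5′ signal, scored 0.405 without a deletion, widening the range of the day 2 controls from 0.106 to 0.599. The Traf2 probe set goes with the labels, being lower in the Traf2 than in the Traf3 knockout array on both days (0.762 against 1.19, and 0.935 against 1.11), though control 5 stood at 0.694. An exchange would leave the combined fold changes as they are. It would change the spread, and with it the standard errors and calls, which were not counted for that case.

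Whether chance could give the results was tested by other splits of the same samples. For both knockouts combined, 3 of 100 splits of the 9 arrays, the real one included, gave at least the real 166 genes. The others gave 2466 and 185. The split with 2466 genes left control 5 alone against the 4 other arrays of day 2, and its count points to a structure of the samples. Over the 60 splits within days only the real 1 gave as many, the highest other giving 151 and being nearly the real one mirrored. In both sets of splits the arrays of an assigned genotype could share a day, unlike the real ones. These shares make chance unlikely as the source of the count but cannot exclude it. For the difference between knockout and transgene effects, 3 of 100 splits of both experiments at once gave at least the real 7 genes, the highest other giving 16, but an effect of the transgene alone would give this too. With the day 3 labels kept, 33 of the 60 splits within days gave at least 7 genes and the highest other 99. The transgene effect stays in each of these splits, so this count cannot decide whether chance gave the knockout part. For the lists called in the knockouts chance cannot be excluded, with 25 of 100 splits giving at least the real 7 and the highest other 11. The 10 splits of day 3 are too few for a share under 0.05; the real 1 gave 35 genes and 7 lists, the highest other 1 gene and 6 lists.

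Knockout and transgene effects differed, as knockout minus transgene on the log2 scale, by -1.50 for Ap1s3, 1.69 for Col23a1, 2.29 for Il9r, -2.27 for Prelid2, 1.75 for Pygl, 2.53 for Runx1 and -2.36 for Sh2b2. The lists that differed between the same effects had medians of 0.20 (marginal zone), -0.22 (germinal centre), -0.14 (cell cycle), 0.16 (B cell identity), 0.18 (MHC class II), -0.14 (interferon), -0.49 (immediate-early and stress), -0.081 (T cell) and -0.10 (NK cell); none passed with an estimated correlation (adjusted p = 0.275 or higher). Between the Traf2 and Traf3 knockouts, plasma cell, germinal centre, cell cycle and glycolysis genes differed by -0.10, -0.11, -0.15 and -0.097 (adjusted p = 0.859 or higher with an estimated correlation). Between days 2 and 1, the knockout effect on B cell identity, MHC class II and interferon genes differed by 0.18, 0.24 and 0.30 (adjusted p = 0.843 for each with an estimated correlation). The immediate-early and stress list lay below every same-day control in 3 of 4 knockout arrays and above every wildtype array in 2 of 3 Baff-transgenic arrays. The remaining one, mouse 1, lay at -0.263, below the lowest wildtype array at -0.245. The list's mean change in the knockouts was -0.398, same-day controls spanned up to 0.823 (0.139 without both arrays high in heat-shock transcripts), and its median without these arrays was -0.31 (camera adjusted p = 7.95e-09, and adjusted p = 0.321 with an estimated correlation).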

How the results depend on the processing

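Leaving out control 5 for the Baff transgene, leaving out both arrays high in heat-shock transcripts, the 5′ over 3′ covariate and every probe set on its own were tests chosen after the data were seen. Counts of genes are given in the order Traf2 knockout, Traf3 knockout, Baff transgene, both knockouts and knockout minus transgene, from 66, 61, 35, 166 and 7. Quantile normalization gave 23, 22, 12, 71 and 1, and median centring 66, 61, 35, 162 and 7. Both were run on the log2 ratios, which were already divided by the same-day control median. Separate fits for days 1 and 2 and for day 3, with fewer arrays behind each spread, gave 23, 5, 94 and 50 in the first 4. The mean of all probe sets gave 97, 112, 53, 258 and 15, and array weights 123, 20, 135, 135 and 17. Day 1 alone gave 20, 9 and 31 for Traf2, Traf3 and both knockouts, and day 2 alone 21, 30 and 38, with 1 knockout array per genotype. Without both heat-shock arrays these 3 counts were 14, 39 and 74. The 5′ over 3′ covariate gave 111, 107, 74, 257 and 12, and every probe set on its own, counting genes with at least 1 call, 122, 105, 66, 238 and 16. Arrays of the compared groups were left out 1 at a time, as was control 5 for the Baff transgene. This gave 16 to 112, 16 to 102, 8 to 74, 89 to 246 and 3 to 12. The highest value came without control 5 each time, but for the Baff transgene no other array of days 1 and 2 was left out. Between the Traf2 and Traf3 knockouts the count went from 0 to between 0 and 2, and between days it stayed at 0 by limma in every alternative run (227 at an unadjusted p under 0.05). The cause of these moves was not tested.

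The lists called in the genotype comparisons went from 31 to between 20 and 38 on leaving out an array, to 0 with an estimated correlation by camera (1081, 1384, 1007 and 1556 genes had an unadjusted p under 0.05 in these comparisons) and to 4 with fry, which tests whether a list's genes move one way and not against other genes. The correlation of Traf2 and Traf3 knockout effects across genes, 0.660 (jackknife SE 0.327), was 0.278 on day 1 alone, 0.282 on day 2 alone and 0.231 in the lowest split of the controls, and 0.408 to 0.711 on leaving out an array. That of knockout and transgene effects, 0.247 (jackknife SE 0.133), stayed between 0.175 and 0.316. The direction turned for interferon genes in the Traf2 knockout, with medians of -0.17 to 0.51 on leaving out an array, the lowest without Traf2 knockout 2, -0.13 on day 1 alone and -0.16 without both heat-shock arrays, for the test on these genes in both knockouts (0.0019 to 0.35, 0.055 and 0.014 in the same order). It also turned for MHC class II genes in the Traf3 knockout, with -0.021 to 0.29 on leaving out an array, the lowest without Traf3 knockout 2, and -0.057 on day 1 alone, and for interferon genes between days, with -0.059 without control 4 to 0.60 without control 3. Other probe sets turned the sign of Rsu1 (-0.097), Cd93 in the Traf2 knockout (0.27, 0.053 and 0.27), the Traf3 knockout (0.048 and 0.097) and both (0.16 and 0.18), Tmco6 (-0.084), Paip1 (-0.12), Epcam (-0.017), Runx1 (0.036 and 0.10), Btg1 (0.070 and 0.059), Sdc1 in the Traf2 knockout (0.17) and both (0.020), Ell2 (-0.049) and Pdia4 (-0.11); the cause was not tested. Of the other values, 719 of lists kept their direction and side of the threshold. Of named genes 2433 stayed on their side of it, those that were not called whatever their sign. Another 280 of lists and 659 of named genes kept the direction only.

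The replicate numbers of wildtype and Baff-transgenic mice did not pair the samples, with correlations of 0.0049, -0.026 and 0.118 between arrays of the same number, and wildtype 1 and 2 correlated best with another number. With the number as a block within day 3, 24 genes passed, 16 higher and 8 lower, against 35. The planned filter on dim probe sets and the prior with an intensity trend were not run, since ratios hold no brightness, so signal over background cannot be given for any gene. Separate fits give no value for knockout minus transgene, and a fit without a day term none for the difference between days.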

Other observations

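The genes below, and the probe sets without a listed gene, were chosen after their values were seen.

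With both knockouts combined, Naip2, a sensor component of the inflammasome, rose 1.74-fold (log2 0.80, SE 0.091, adjusted p = 0.000513), Cd59a, an inhibitor of complement lysis, 2.03-fold (1.02, SE 0.123, adjusted p = 0.000824), and Ptpn22, a lymphoid phosphatase that dampens antigen receptor signals, 1.98-fold (0.99, SE 0.151, adjusted p = 0.00474). These 3 calls held whichever control or knockout array was left out. Il12a, a cytokine subunit gene, rose 2.55-fold (adjusted p = 0.0361), but its call ended without control 2, control 3, either Traf2 knockout or Traf3 knockout 2. Mpeg1, which encodes a pore-forming protein of phagocytes, rose 2.41-fold (adjusted p = 0.0362), and its call ended without control 2, control 3, Traf2 knockout 2 or either Traf3 knockout. Coro1a, an actin regulator of leukocytes, fell to 0.652 of the control level (adjusted p = 0.00796), a call that ended without Traf2 knockout 2, and Slamf9 fell to 0.665 (adjusted p = 0.00988), a call that ended without knockout 2 of either genotype.

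Anxa4, a calcium-dependent membrane-binding protein gene, rose 2.37-fold in both knockouts combined (log2 1.25, SE 0.0916, adjusted p = 1.12e-05), Plbd1, a phospholipase-like gene, 2.15-fold (1.10, SE 0.142, adjusted p = 0.00145) and Kynu, which encodes kynureninase of tryptophan breakdown, 1.82-fold (0.86, SE 0.122, adjusted p = 0.00284). All 3 calls held whichever control or knockout array was left out. Of 9160 probe sets without a listed gene, 8 passed in the Traf2 knockout, 5 in the Traf3 knockout, 14 in both combined and 2 in the Baff-transgenic mice.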
